A study of Mus musculus with 12 samples.

How the data were processed

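The measurement was droplet-based single-cell RNA sequencing of mouse small intestinal epithelium, read from the 3′ end of transcripts. Per the labels' protocols, the intestine of adult mice of an Lgr5 reporter strain (Lgr5DTR-GFP) was divided into 30 equal pieces. Cells of each piece were tagged with a MULTI-seq barcode, a lipid-anchored DNA oligonucleotide that marks a cell's origin, and were then sorted and pooled. The series has 12 samples in 3 groups. The 8 samples of the diet group held sorted epithelial cells (negative for CD45, positive for EpCAM), and the labels do not name the diet of any of them. The 2 total epithelium samples and the 2 progenitor samples were not analysed here.

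Per the submitters' processing notes, Cell Ranger and the mouse build mm10 were used. The Cell Ranger version and any cell filter or merging step are not given in the sources used here. The authors' deposited table held 20090 genes and 27881 cells, and its values were treated as a score (the unit given to numbers with no fixed scale), not as counts. The values were whole numbers, but in 25.3% of cells the value 2 was more frequent than 1, and cell totals spanned only 2764 to 9739. Raw molecule counts do not behave in this way, and the step that made the values is not given in the sources used here. The depth behind each value was therefore unknown, and expression values carry no counting interval. The segment barcode and the diet of each cell were not used here.

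Cell barcodes ended in 1 of 8 numbers, which did not match the numbering of the sample titles. The table was therefore treated as 1 pooled sample, and the 8 barcode sets are given as values, medians and ranges, with no test between them. Between different sets, 80 pairs of barcodes were shared, and 27802 barcodes were distinct. A set held 2286 to 5320 cells with median cell totals of 4747.5 to 6147 and median detected genes of 1693.5 to 2576. Nothing in the sources used here says that the sets came from separate animals.

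Cells with at least 500 detected genes and at most 25% mitochondrial transcripts were kept, which removed 2 cells. Doublets were called per set with Scrublet in scanpy 1.11.5 (expected rate 0.06). The caller marked 45 cells (0.161%), below the 0.5% set here as the least for a working caller. Whether it failed or doublets had been removed before deposit is not known, so doublets may remain beyond the 45 removed. The remaining 27834 cells were scaled to a common total, log-transformed, reduced to 30 principal components of 2000 variable genes and clustered with leidenalg 0.10.2 (15 neighbours, resolution 1). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.

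Clusters were named from 13 marker lists. A cluster took a name where at least 3 markers of a list were at least 2-fold higher than in all other cells, at 10 ppm or more (ppm is the part a gene takes of the summed values of all genes). The median log2 fold of that list also had to exceed that of any rival list by at least 0.5, except that stem and transit-amplifying lists both gave the name progenitor-like. A cluster with at least 3 of 4 stomach genes among its 10 leading genes was left unnamed. These thresholds and the stomach rule were set after the clusters had been seen, and 8 of 25 clusters stayed unnamed. Fabp1, Fabp6, Lct, Sis and Apoa1 are among the enterocyte markers as well as in lists compared below. Shares have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only.

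Position along the intestine was estimated, not read from a barcode. A regional score was the mean of log1p values per 10000 over 8 distal scoring genes (Clec2h, Naaladl1, Tmigd1, Prss30, Muc3, Plb1, Cubn, Amn) minus that over 8 proximal scoring genes (Gsta1, Adh6a, Ms4a10, Cyp2d26, Hsd17b6, Gda, Cyp2c66, Cyp2b10). Cells of a class were divided into 3 equal parts of the score, proximal, middle and distal, within each barcode set, with ties broken at random. The parts are ranges of a score and not cell types. Of enterocyte-like cells, 15.5% lay within 0.1 SD of a boundary between parts, and of progenitor-like cells 48.0%. The 16 scoring genes stayed out of all results, but relatives of some did not. Among these were relatives of Gsta1 (Gsta4 and Gm3776), of Cyp2c66 (Cyp2c65 and Cyp2c55) and of Adh6a (Adh1).

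Values were summed over the cells of a part and scaled to ppm, and the log2 difference of the distal and proximal parts was taken with a pseudocount of 1 ppm. It understates differences of low genes. The count test foreseen for raw counts was replaced by the description foreseen for other values, with no test and no p-value. A gene was called higher in a part where the mean of both ends was at least 10 ppm, the absolute log2 difference was at least 1 and all 8 barcode sets had the same direction. Chance alone gives the same direction in all 8 sets for 0.781% of genes. This size rule was set once the unit was known and before any regional result was seen. The same sets supply the cells of both ends, and the score itself reads genes that vary with others, so the rule describes this table.

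The 15 gene lists, the marker lists, the scoring genes and the rule for naming genes were fixed before the data were examined. From each list, up to 2 members at 10 ppm or more with the largest absolute difference were named, and outside the lists 4 genes in each direction at 50 ppm or more. Genes named to complete a short count, and genes named in the closing paragraphs, were chosen after their values were seen. The values of a few single genes are not reported here. A list's median was placed among 10000 random lists of the same size matched on mean level, and a list was called where it lay outside the middle 95% of the random lists. These percentiles describe these cells and are not p-values.

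In a simulation, cells of each class were put in parts at random and differences were planted in 200 genes. The rule recovered 0% of 1.5-fold, 32% of 2-fold, 100% of 3-fold and 100% of 4-fold differences in enterocyte-like cells (7823 genes). In progenitor-like cells (9562 genes) it recovered 0%, 32%, 96% and 100%. A 1.5-fold difference lies below the size rule, which largely set its 0% in advance. The same fold was planted in every barcode set, so recovery of differences that vary between sets was not measured. None of the genes left unplanted was called. Random parts lack the differences in detected genes and clusters that parts cut by the score have. The simulation therefore gives no rate of false calls for parts cut by the score. Alternatives covered the cell filter, the clustering, doublets, the score, the pseudocount, the low-value filter and each barcode set left out in turn, and 8 more were added after the data had been seen. Gene positions are from GENCODE M21 (GRCm38, the assembly also called mm10), in which 98.1% of the symbols were found. The deposited table gives gene symbols only. Transcripts of near-identical family members (Reg3a, Reg3b and Reg3g; Saa1 and Saa2; Gsta genes and Gm3776; Cyp4a10 and its relatives) can be exchanged in counting, and their values are uncertain to that extent.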

Results

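The data were single-cell transcriptomes of sorted mouse small intestinal epithelium from the 8 libraries of a diet series. One table pooled 27881 cells in 8 barcode sets, with a median summed value of 5503 units and 2219 detected genes per cell. The diet of each library is not named in the labels, so diets were not compared. The design text describes sampling of 30 segments over the length of 2 small intestines. The questions addressed here were which epithelial cells the table holds, which genes differ between proximal-like and distal-like enterocytes, and whether those differences are already present in crypt progenitors.

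Progenitor-like and enterocyte-like cells made up most of the cells that could be named. Progenitor-like cells, which combine stem-like and transit-amplifying-like clusters of the crypt, were 33.2% of 27834 cells (95% interval 32.7 to 33.8, 9249 cells). Enterocyte-like cells, the absorptive cells of the villus, were 24.04% (23.5 to 24.5, 6691 cells). Goblet-like cells, which secrete mucus, were 3.39% (3.18 to 3.61). Tuft-like cells, chemosensory cells marked by Dclk1 and Pou2f3, were 1.49% (1.35 to 1.64), and hormone-producing enteroendocrine-like cells were 1.29% (1.16 to 1.43). The remaining 36.5% (10159 cells) were in clusters that met no naming rule. The smaller shares depended on the clustering. At resolution 0.5 no goblet-like cluster was named and enteroendocrine-like cells were 0.111%, and at resolution 2 these classes were 5.42% and 3.25%.

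Goblet-like cells were concentrated in barcode set 4, where set 7 held 75 of them (1.41% of its cells). Tuft-like and enteroendocrine-like cells were concentrated in sets 4 and 7. Set 4 held 771 of the 944 goblet-like cells, 33.8% of its cells, and the median over the 8 sets was 0.687% with a lowest value of 0.0218%. Set 7 held 318 of the 415 tuft-like cells and set 4 held 71. Enteroendocrine-like cells numbered 199 in set 7 and 56 in set 4 of 358 in total. Enterocyte-like cells ranged from 4.89% to 50.6% of a set (median 26.5%) and progenitor-like cells from 7.68% to 51.3% (median 33.8%). Unnamed cells ranged from 18.9% to 52.0% of a set (median 34.4%). The largest unnamed cluster, led by Agr2, Spink4, Mmp7, Sst and the globin gene Hbb-bs, made up 43.3% of set 7. No Paneth-like cluster was named at this resolution, and at resolution 2 a Paneth-like class held 617 cells (2.22%). These shares depend on the sort, the loading of each library and the clustering, and the sets could not be assigned to diets.

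**Figure D1:**
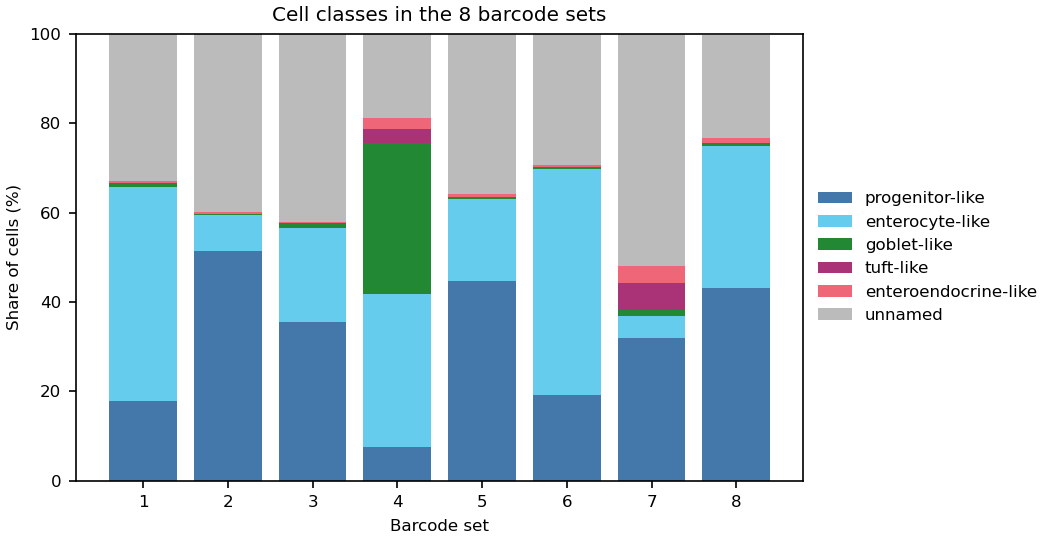
Share of cells (%, vertical axis) of each class in the 8 barcode sets (horizontal axis), as stacked bars that start at 0; the 18 T cell-like cells are left out. Goblet-like cells form 33.8% of set 4, and tuft-like cells reach 5.98% in set 7.

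Enteroendocrine-like cells carried transcripts of several gut hormones. All genes given in this paragraph are among the markers that named this class, so a higher share in it was partly set by the naming. Gip, the incretin of K cells, had a value in 85.5% of them, against 60.8% of enterocyte-like cells, which should lack it. Secretin (Sct) had a value in 68.2% against 42.2%, somatostatin (Sst) in 40.5% against 28.2%, cholecystokinin (Cck) in 38.5% against 14.6% and Pyy in 29.6% against 10.4%. Tph1, the enzyme of serotonin synthesis in enterochromaffin cells, had a value in 10.6% against 2.66%, and proglucagon (Gcg) in 8.94% against 3.29%. Neurotensin (Nts) had a value in 19.6% against 22.7%. Sets 4 and 7 held 255 of the 358 enteroendocrine-like cells but 1036 of the 6691 enterocyte-like cells. With the background of each set weighted by its enteroendocrine-like cells, it was 66.3% for Gip, 37.0% for Sct, 32.8% for Sst, 13.5% for Nts, 9.57% for Pyy, 8.08% for Cck, 3.26% for Gcg and 3.04% for Tph1. The share was above that of enterocyte-like cells of the same set in all 8 sets for Sct, Cck, Gcg and Tph1, in 7 for Pyy, in 6 for Sst and Nts and in 4 for Gip. Median detected genes were 1717 in enteroendocrine-like and 1939 in enterocyte-like cells, and the shares in enterocyte-like cells show that hormone transcripts were spread over cells of another class.

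Enterocyte-like cells differed widely along the regional score. Of 7899 genes considered, 612 were higher in the distal part and 1080 in the proximal part, and 1515 of these 1692 had an intermediate level in the middle part. The list medians of bile acid uptake, peptide uptake, MHC class II and antimicrobial defence lay above the range of random lists, and those of iron and calcium uptake, retinoid metabolism, carbohydrate uptake and fatty acid oxidation lay below it. Part of the members of each list passed the rule. The parts held 2234, 2231 and 2226 cells. Direction was the same in all 8 barcode sets for 52.6% of genes, and no gene passed the rule in any of 20 random divisions of the same cells. Random parts are alike in detected genes and clusters. They show only that the drawing of cells did not pass the rule, not that the differences are regional.

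Bile acid genes had a median log2 difference of 1.70 (1.49 to 1.96 over the 8 sets, above all 10000 random lists). Of 7 members, 5 were higher distally and 1 proximally. Fabp6, the ileal bile acid-binding protein (chromosome 11, 43596049 to 43601540, minus strand, GRCm38), was at 253 ppm proximally and 11005 distally, a log2 difference of 5.44. Slc10a2, the apical sodium-dependent bile acid transporter (chromosome 8, 5083219 to 5105351, minus strand), was at 8.09 and 372 ppm, a difference of 5.36. The other distal members were Fgf15, the enterokine that represses hepatic bile acid synthesis (4.64), the bile acid receptor gene Nr1h4 (1.70) and Slc51a, a subunit of the basolateral exporter (1.503). Nr0b2, a transcriptional repressor induced by that receptor, was higher proximally (-1.78).

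Peptide and amino acid uptake genes had a distal median of 1.11 (percentile 99.99), with 9 of 17 members higher distally and none proximally. Mep1a, a subunit of the brush border metalloprotease meprin, differed by 2.80 and the aminopeptidase gene Xpnpep2 by 2.64. Cholesterol genes had a median of 0.77 (percentile 99.85), with 4 of 15 members higher distally. Among these were Sqle of the synthesis pathway (1.52), the exporter gene Abca1 (1.38) and the cholesterol uptake gene Npc1l1 (1.37). With the proximal scoring genes alone, the peptide median was 0.22, and without rescaling the cholesterol median was 0.34.

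MHC class II genes had a median of 1.30 (0.45 to 2.69 over sets, percentile 99.98), with 3 of 5 members higher distally. Cd74, the invariant chain, differed by 2.07, H2-Aa by 1.73 and H2-Ab1 by 1.30. Antimicrobial and barrier genes had a median of 1.21 (0.44 to 1.37 over sets), with 6 of 10 members higher distally and 3 proximally. Saa1, a serum amyloid A gene, was at 2.67 and 163 ppm (5.48). Reg3a, a C-type lectin gene, was lower distally (-2.95). Cluster 22, led by the inflammatory genes Nos2, Ccl20 and Ubd and by H2-Aa, was 1.43% of the proximal, 6.68% of the middle and 3.77% of the distal part. With the proximal scoring genes alone the MHC class II median was -0.02 and the antimicrobial median 0.51, and with the distal scoring genes alone or the stricter cell filter the MHC class II median was 2.10 and 2.09.

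The lists for mineral, vitamin A and sugar handling had medians below 0. The iron, calcium and folate list had a median of -2.01 (-2.67 to -1.53 over sets, below all 10000 random lists), with 4 of 6 members higher proximally. S100g, the calcium-binding protein calbindin-D9k (chromosome X, 162961992 to 162964599, minus strand), was at 1306 ppm proximally and 25.5 distally (-5.62). Slc40a1, the iron exporter ferroportin, differed by -3.36, the folate transporter gene Slc46a1 by -2.84 and the iron importer gene Slc11a2 by -1.17. Retinoid genes had a median of -1.85, with 4 of 7 members higher proximally. Rbp2, the cellular retinol-binding protein of enterocytes (chromosome 9, 98486115 to 98509781, plus strand), was at 13824 and 2385 ppm (-2.53), the retinol dehydrogenase gene Rdh7 differed by -2.54, Retsat by -2.22 and Aldh1a1 by -1.85. Carbohydrate genes had a median of -1.40, with 7 of 12 members higher proximally, among them the gluconeogenic enzyme gene Fbp1 (-2.98) and the basolateral sugar transporter gene Slc2a2 (-2.14). The retinoid median was -0.83 with cells matched on detected genes, and with the distal scoring genes alone it was -1.20 and the carbohydrate median -0.89.

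The fatty acid and drug metabolism lists also had medians below 0. Fatty acid oxidation and ketogenesis had a median of -1.10, below all random lists, with 10 of 16 members higher proximally and none distally. The omega-hydroxylase gene Cyp4a10 differed by -4.86 and the thiolase gene Acaa2 by -2.64. Lipid absorption had a median of -0.78 (percentile 0.23), with 7 of 18 members higher proximally. Fabp1, the liver-type fatty acid-binding protein (chromosome 6, 71199827 to 71205023, plus strand), was at 25396 and 2593 ppm (-3.29), and the fatty acid receptor gene Cd36 differed by -2.78. Apoa1, the main protein of high-density lipoprotein, was the only member of that list higher distally (1.01). Drug metabolism had a median of -0.68 (percentile 0.94), with 5 of 12 members higher proximally and 1 distally. Among the proximal members, Cyp2c65 (-1.97) is a relative of the scoring gene Cyp2c66, and Gsta4 of Gsta1. The list was therefore not independent of the score. The glutathione transferase genes Gsta4 (-4.25) and Gstm3 (-3.91) were proximal, and Abcb1a, which encodes a drug efflux pump, was distal (1.80). With the distal scoring genes alone the drug median was -0.03 and the lipid median -0.36, and the drug median was -1.34 with the proximal scoring genes alone and -1.10 without rescaling. With cells matched on detected genes the fatty acid oxidation median was -0.55 and the lipid median -0.49.

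Regional transcription factors and stem genes went both ways. The list median was 0.54 (percentile 94.08) and the mean -0.10, with 4 of 12 members higher distally and 3 proximally. The median was 0.03 with the proximal scoring genes alone, 0.15 without rescaling and 0.33 with unnamed clusters 9, 12 and 18 added. Pdx1, a duodenal homeobox factor (-4.02), Onecut2 (-3.66; chromosome 18, 64340020 to 64400987, plus strand) and Gata4, a factor of the proximal small intestine (-1.27), were proximal. Osr2 (1.40), Tbx3 (1.23) and Hnf4a (1.16), which encode transcription factors, were among the distal members. Outside the lists, Reg1, a member of the regenerating gene family (chromosome 6, 78422711 to 78428667, plus strand), was at 6504 and 60.4 ppm (-6.73). Sult6b2 of the sulfotransferase family (-6.09) and the lipolysis inhibitor gene G0s2 (-6.08) were also proximal. Gm3776 of the glutathione transferase family was at -5.31. Its transcripts can be exchanged with those of the scoring gene Gsta1, and its difference moved by less than the spread of the barcode sets with the distal scoring genes alone, which leave Gsta1 out of the score. The distal genes were the magnesium channel gene Trpm6 (3.82), Gsdme of the gasdermin family (3.65), the monocarboxylate transporter gene Slc5a8 (3.25) and the glutamate receptor subunit gene Grin2a (3.16).

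The villus tip list was compared between the ends of the score. Its median was 1.19 (0.37 to 4.35 over sets), with 4 of 6 members higher distally. The nucleoside transporter gene Slc28a2 was at 214 ppm proximally, 1033 in the middle part and 524 distally (1.29), and Klf4, a factor of differentiated epithelium, was at 112, 372 and 354 (1.65). Nt5e (1.26) and Egfr (1.12) were the other members past the rule. Cluster 6, led by Nt5e, Ada and Slc28a2, was 11.1% of the proximal, 43.4% of the middle and 23.8% of the distal part. The villus tip median was 3.08 with the proximal scoring genes alone, 2.81 with the stricter cell filter, -0.74 with the distal scoring genes alone and -0.61 with cells matched on detected genes. Slc28a2 was at -1.34 and -0.86 in the last 2 of these.

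The dissociation stress list (median 0.47, percentile 92.9) and the housekeeping list (-0.13, percentile 29.45) were within the range of random lists. In the stress list, the immediate early genes Jun (1.23), Atf3 (1.22), Junb (1.17) and Fos (1.08) were higher distally, and the heat shock gene Hspa1a was lower (-1.22). The stress median and Atf3 were both at -0.16 with the distal scoring genes alone, and the stress median was 0.80 with the proximal scoring genes alone and 0.08 without rescaling. Among housekeeping genes, the glycolytic gene Gapdh was higher proximally (-1.18), and the list median was -0.41 with the distal scoring genes alone and -0.52 without rescaling.

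The enterocyte parts differed in composition and in detected genes. Clusters 13 (41.1%) and 15 (34.5%) supplied most of the proximal part, and clusters 16 (35.0%), 6 (23.8%), 11 (19.7%) and 17 (17.3%) most of the distal part. Median detected genes were 2706 proximally and 1691 distally. Summed markers of other classes were higher distally, by 1.55 for stem, 1.05 for transit-amplifying, 1.32 for goblet, 1.65 for Paneth and 1.28 for enteroendocrine markers, each in all 8 sets. As medians over cells, goblet markers were at 1333 and 4609 ppm and Paneth markers at 853 and 4069. Markers of cells outside the epithelium were low, with sums of at most 10.3 ppm at either end, and differed by -0.01 (T cell), 0.38 (B or plasma cell), -0.80 (myeloid), -0.02 (stromal), -0.21 (endothelial) and -0.05 (red blood cell). The sum of tuft markers was lower distally (-1.77), and without Ltc4s, a leukotriene synthase gene that was itself at 91.1 and 7.40 ppm, it was higher (0.46).

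Most enterocyte differences kept their direction under changes of the score, and fewer stayed past the rule. With the proximal or the distal scoring genes alone, 1668 of the 1692 genes kept their direction under both, and 1354 with the proximal and 919 with the distal scoring genes alone were still past the rule. The distal scoring genes alone gave 329 distal and 699 proximal genes, the stricter cell filter 935 distal genes and a pseudocount of 10 ppm 662 proximal genes. With proximal and distal cells matched on detected genes, 300 genes were higher distally and 479 proximally; 1674 of the 1692 kept their direction and 692 were still past the rule. Without rescaling to a common total, 250 genes were higher distally and 1938 proximally, as the median of all genes moved from -0.06 to -0.44.

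**Figure D2:**
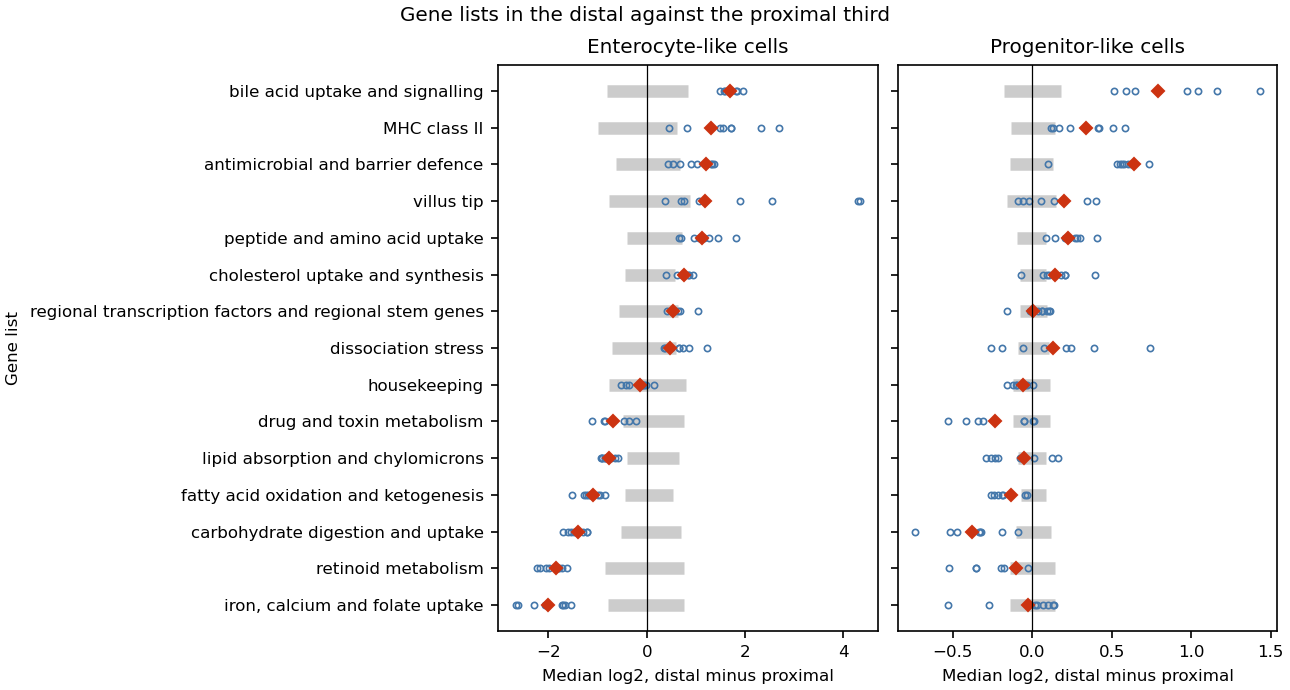
Median log2 difference, distal minus proximal part (horizontal axes, which differ in scale), of the 15 gene lists (vertical axis) in enterocyte-like (left) and progenitor-like cells (right); red diamonds are the pooled medians, open blue circles the 8 barcode sets, and grey bars span the middle 95% of random lists. In enterocyte-like cells the medians run from -2.01 to 1.70, and in progenitor-like cells from -0.38 to 0.79.

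Progenitor-like cells were divided by the same score, which was 0 in 41.2% of them against 0.269% of enterocyte-like cells, so many were placed at random and the numbers of genes in the classes were not compared. Of 9561 genes considered, 9 were higher in the distal part and 12 in the proximal part, and 8.97% of genes had the same direction in all 8 sets. Of these 21 genes Fabp6 had the largest distal difference, at 50.2 ppm proximally and 274 distally (2.42). The antimicrobial lectin genes Reg3g (1.29; chromosome 6, 78466269 to 78468872, minus strand) and Reg3b (1.28; chromosome 6, 78370657 to 78373466, plus strand) and the oxidase gene Duox2 (1.17) were distal. Reg1 (-1.98), Onecut2 (-1.44), S100g (-1.27), the arginase gene Arg2 (-1.25), Gstm3 (-1.24), Fabp1 (-1.19) and the regional stem gene Gkn3 (-1.16) were proximal. The parts held 3086, 3083 and 3080 cells, and no gene passed the rule in any of 20 random divisions, with the same limit as for enterocyte-like cells.

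By list, bile acid genes had a median of 0.79 (0.51 to 1.43 over sets; 3 members measured, 1 past the rule), with the receptor gene Nr1h4 at 0.79. Antimicrobial genes had a median of 0.64 (0.10 to 0.73 over sets) with 3 of 6 members past the rule. MHC class II (0.34), peptide uptake (0.22), villus tip (0.20), cholesterol (0.15) and stress genes (0.13) also lay above the range of random lists, with no member past the rule. Over sets, the villus tip median ran from -0.09 to 0.40 and was above 0 in 5 of 8, cholesterol from -0.07 to 0.40 (7 of 8) and stress from -0.26 to 0.74 (5 of 8). Markers of myeloid cells, which also carry MHC class II, were at 15.4 ppm proximally and 22.7 distally (0.53, higher distally in 7 of 8 sets). The peptidase gene Enpep was at 0.76, Mep1a at 0.64, Cd74 at 0.42, H2-DMa at 0.36, Klf4 at 0.54, Ada, an adenosine deaminase gene, at 0.21, Npc1l1 at 0.23, Egr1 at 0.34 and Fos at 0.32. Carbohydrate (-0.38), drug metabolism (-0.23) and fatty acid oxidation genes (-0.14) lay below the range of random lists, and the drug median ran from -0.53 to 0.01 over sets. Their leading members included the sucrase-isomaltase gene Sis (-0.88), the ketohexokinase gene Khk (-0.87), Gstm1 (-0.63) and the thioesterase gene Acot1 (-0.78). Sis was lowest in the middle part (134 ppm proximally, 39.7 in the middle and 72.5 distally), as was Enpep (26.4, 17.6 and 45.6).

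Most of these list medians changed sign with 1 side of the score. With the proximal scoring genes alone, the medians were -0.60 for bile acid, -0.17 for antimicrobial, -0.82 for peptide, -0.28 for cholesterol, -0.26 for villus tip, -0.70 for carbohydrate and -0.69 for drug metabolism genes, and Nr1h4, Enpep, Mep1a, Npc1l1, Klf4 and Ada were below 0. With the distal scoring genes alone, they were 0.30 for carbohydrate, 0.47 for drug metabolism, 0.10 for fatty acid oxidation, -0.03 for MHC class II, 1.91 for bile acid, 0.94 for peptide, 0.71 for villus tip and 0.47 for cholesterol genes, and Sis and Khk were above 0. The drug median was 0.04 and the peptide median 0.48 with unnamed cluster 2 added, and they were -0.48 and 0.08 without cluster 7. The fatty acid oxidation median was -0.045 without rescaling and -0.23 with the stricter cell filter, and the antimicrobial median was 0.42 with the score read from cells thinned to 3000 units.

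Retinoid (-0.10), lipid absorption (-0.05), iron and calcium (-0.03), housekeeping (-0.06) and regional transcription factor lists (0.00) were within the random range. Their largest members included Rbp2 (-0.94), Rdh7 (-0.75), the transcription factor gene Creb3l3 (-0.72), Slc40a1 (-0.41), Gapdh (-0.22) and Tpt1 (-0.15). Outside the lists, Klf12 (0.83), 1700025G04Rik (0.68), the annexin gene Anxa2 (0.63) and the adenylate cyclase gene Adcy8 (0.62) had the largest distal differences at 50 ppm or more, and Prdm16, a transcriptional regulator gene (-0.87), and Prap1 (-0.85) followed Reg1 and Arg2 among proximal genes. None of these 6 was past the rule. The lipid (0.81), iron and calcium (0.38) and retinoid medians (0.30) were above 0 with the distal scoring genes alone, as were Rbp2, Creb3l3, Slc40a1 and Gapdh, and with the proximal scoring genes alone Anxa2 was below 0.

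The progenitor differences depended on which scoring genes were used. Distal and proximal genes numbered 2 and 6 when the score was read from cells thinned to 3000 units, and 15 and 27 between the outer 2 of 4 parts of the score. Without barcode set 7, 14 genes were higher distally, and with a pseudocount of 10 ppm 5 were. The stricter cell filter gave 19 proximal genes, and 20 were proximal without cluster 7. With the proximal scoring genes alone, 0 genes were higher distally and 56 proximally, and Fabp6 was at -0.60. With the distal scoring genes alone, 51 were higher distally and 6 proximally, and Fabp1 was at 0.23. Of the 21 genes, 5 kept their direction under both, namely the homeobox gene Meis2, Duox2, Gstm3, the alcohol dehydrogenase gene Adh1 and Onecut2, and Gstm3 was at -0.01 with the distal genes alone. The sum of enterocyte markers was at -0.14 with both, -0.85 with the proximal and 0.70 with the distal scoring genes alone. Cluster 7, rich in mitochondrial transcripts, was 11.9% of the proximal and 21.6% of the distal part. Cluster 3 was 24.6% and 30.5%, and cluster 5, in which 13 of 13 stem markers were raised, was 22.0% and 14.1%. Summed stem markers differed by -0.15 and were higher distally in 2 of 8 sets, and this was not separated from the difference of Gkn3. Goblet (0.37), Paneth (0.31) and enteroendocrine markers (0.26) were higher distally in all 8 sets. Apart from myeloid markers, the lists of cells outside the epithelium, at sums of at most 8.39 ppm, differed by 0.47 (stromal), 0.22 (red blood cell), 0.14 (B or plasma cell), -0.10 (T cell) and -0.25 (endothelial).

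The differences of both classes were set side by side. Over 7254 genes considered in both, Pearson's correlation across genes was 0.54 and Spearman's 0.50, and genes are not independent replicates. Of 18 genes past the rule in progenitor-like cells among these, 17 were also past it in enterocyte-like cells in the same direction. The same scoring genes ordered both classes, so this overlap was not set against chance, and 16 of all 21 progenitor genes lost their direction with 1 side of the score. The difference between the classes was not tested.

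**Figure D3:**
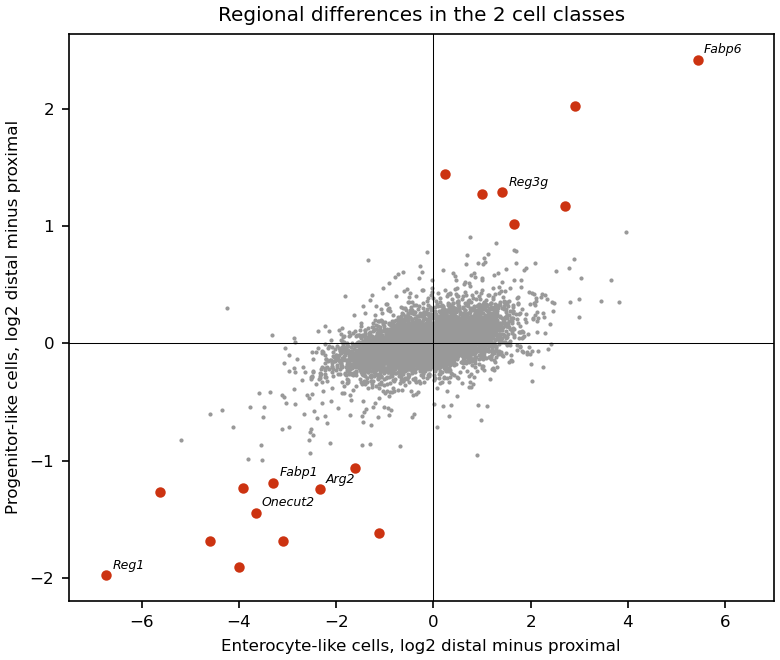
Log2 difference, distal minus proximal part, in enterocyte-like (horizontal axis) and progenitor-like cells (vertical axis, on another scale); each point is a gene at 10 ppm or more in both classes, and red points passed the rule in progenitor-like cells. Fabp6 lies at 5.44 and 2.42 and Reg1 at -6.73 and -1.98.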

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

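The 3 patterns weighed here were noticed in these data, and the tests were chosen after that. The bounds of the tests were set before their results were seen, except for the number of secretory cells outside sets 4 and 7, whose bound of 3 cells was set after the numbers were known. Matching on detected genes was at first drawn once (0.47), and the median of 20 draws was adopted after that value was seen.

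Markers of other lineages were higher in the distal part of enterocyte-like cells, with a median log2 difference of 1.32 over 5 marker sums. Free RNA that weighs more in cells with fewer detected genes may account for part of the pattern, since matching on detected genes brought the median to 0.436 (0.33 to 0.50 over 20 draws), below the bound of 0.5 in the median draw and at it in the highest. All 5 sums stayed above 0 after matching, from 0.29 for goblet to 0.68 for stem markers, so a part stays open. Without matching, the median was 1.69 with the proximal and 0.67 with the distal scoring genes alone, so the choice of scoring genes also moved it. For doublets with crypt cells, the median was 1.36 without the 5% of cells with the highest doublet scores. The caller that gave these scores marked 0.161% of cells, too few for a test. Medians over cells were also higher distally for all 5 lists. From proximal to distal they were 853 and 4069 ppm (Paneth), 1333 and 4609 (goblet), 163 and 711 (stem), 350 and 874 (enteroendocrine) and 151 and 320 (transit-amplifying). This argues against doublets in a small share of cells as the only cause, and a larger share stays open. No biological explanation was tested, because the labels give no group within these cells.

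Tuft-like and enteroendocrine-like cells were concentrated in barcode sets 4 and 7, and goblet-like cells in set 4 (33.8%) but not in set 7 (1.41%). The 3 classes were weighed together, except in the count of tuft markers. Cells hidden in other clusters were argued against as the cause for tuft-like cells only. Cells with at least 3 tuft markers, counted without clusters, were 8.16 times as frequent in the lower of these sets as in the highest other set (2.27% against 0.279%). For goblet-like and enteroendocrine-like cells no such count was made, and hidden cells stay open. The largest unnamed cluster, with 2304 of its 2822 cells in set 7, was led by genes that included Agr2 and Sst. At resolution 2, Agr2 was among the leading genes of a goblet-like cluster of 611 cells, and Sst of an enteroendocrine-like cluster of 744. A sort or filter that differed before deposit could not be told apart from other causes, since the other sets held up to 54 cells of these classes, which is neither near 0 nor a like share. Different diets or animals may also differ in these classes, but the labels tie no set to a diet, and no biological explanation was tested.

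Mitochondrially encoded transcripts were higher in the distal part of progenitor-like cells (0.19) and lower in the distal part of enterocyte-like cells (-0.48). Fewer detected genes in distal enterocyte-like cells were argued against as the cause there, since the difference was -0.486 after matching (-0.50 to -0.47 over 20 draws). In progenitor-like cells, a larger share of cluster 7 in the distal part may contribute, as the difference was 0.106 without that cluster, between the bounds set for and against it, so the question stays open. No biological explanation was tested.

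Of 113 values tested over the 8 barcode sets, 8 had a set far from the others by Dixon's criterion (0.526), and chance marks about 1 in 20. Set 4 stood apart in its goblet-like share of 33.8%, in the antimicrobial median of progenitor-like cells (0.10) and in the regional factor median of progenitor-like cells (-0.16). Set 7 stood apart in the regional factor median of enterocyte-like cells (1.05) and in S100g of enterocyte-like cells (-7.61). Set 4 held the fewest progenitor-like cells of any set (175) and set 7 the fewest enterocyte-like cells (260), so these expression values rest on few cells. In progenitor-like cells, set 1 stood apart in Rdh7 (-1.68), set 8 in Ada (0.70) and set 2 in 1700025G04Rik (1.11).

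Cells outside the comparisons also gave a signal, above the 3 cells that a count of 0 allows. A cluster of 171 cells (0.614%) was led by the stomach surface genes Tff1, Gkn1, Gkn2 and Muc5ac. A T cell-like cluster of 18 cells (0.0647%) was led by Gzma and Ccl5, although the sort selected cells negative for CD45.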

How the results depend on the processing

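The alternatives without rescaling, with cells matched on detected genes, with other clusters added or left out, without the highest doublet scores, without barcode sets 4 and 7 and with the hormone background weighted by set were chosen after the data had been seen; the others were planned. No paired analysis was possible because barcode sets could not be matched to the numbered samples, so the sample number could not serve as a block; both ends were compared within each barcode set. The planned count test with other size factors, the count-based gene filter and the fit without a library term were not run, since the values are not counts; a low-value filter of 10 ppm against none stood in for that filter. Of list medians over all alternatives, 564 stayed within the spread of the barcode sets, 68 moved beyond it and 13 medians of called lists changed sign. Of named genes these numbers were 1408, 139 and 11. Called or not, 28 of 645 medians and 27 of 1558 gene values changed sign. Of gene numbers, 66 stayed within 1.5 times and 20 moved; of shares, 11 and 12; of 8 hormone backgrounds, 2 stayed within their intervals and 6 moved. Unknown depth limits all low values. For every value below, the cause was not tested.

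Shares of enterocyte-like, progenitor-like, enteroendocrine-like and tuft-like cells were 30.4%, 34.3%, 0.111% and 1.22% at resolution 0.5, where no goblet-like cluster was named. At resolution 2, enterocyte-like, progenitor-like, goblet-like and enteroendocrine-like shares were 21.2%, 34.4%, 5.42% and 3.25%, and a Paneth-like class (2.22%) was named. With the stricter cell filter, enterocyte-like, progenitor-like and goblet-like shares were 19.9%, 36.0% and 3.11%. With called doublets kept, the enterocyte-like share was 26.6%.

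In enterocyte-like cells, the stricter cell filter gave 935 distal genes and medians of -0.59 (lipid), 1.46 (bile acid), 2.09 (MHC class II) and 2.81 (villus tip). The outer 2 of 4 parts of the score gave -0.96 (lipid) and 1.95 (bile acid). A pseudocount of 10 gave 662 proximal genes and -1.54 (iron and calcium), and list members from 1 ppm gave -1.41 (iron and calcium).

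With the proximal scoring genes alone, enterocyte medians were 0.57 (cholesterol), -1.71 (carbohydrate), 0.22 (peptide), 1.44 (bile acid), -2.60 (retinoid), -1.34 (drug), 0.51 (antimicrobial), 0.034 (regional factors), 3.08 (villus tip) and 0.80 (stress), and MHC class II changed sign to -0.016. With the distal scoring genes alone there were 329 distal and 699 proximal genes. Medians were -0.36 (lipid), -0.89 (carbohydrate), -1.20 (retinoid), -0.031 (drug), -0.76 (fatty acid oxidation), 2.10 (MHC class II) and -0.41 (housekeeping), and stress (-0.16, not a called list), villus tip (-0.74), Slc28a2 (-1.34) and Atf3 (-0.16) changed sign.

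Without rescaling, 250 genes were distal and 1938 proximal in enterocyte-like cells. Medians were -1.04 (lipid), 0.34 (cholesterol), -1.75 (carbohydrate), 1.29 (bile acid), -2.16 (retinoid), -1.10 (drug), -1.40 (fatty acid oxidation), 0.15 (regional factors), 0.078 (stress) and -0.52 (housekeeping). With matched cells, 300.0 genes were distal and 479 proximal. Medians were -0.49 (lipid), 1.03 (cholesterol), 2.00 (bile acid), -0.83 (retinoid), -0.55 (fatty acid oxidation) and 1.62 (antimicrobial), and villus tip (-0.61) and Slc28a2 (-0.86) changed sign. With unnamed clusters 9, 12 and 18 added, medians were -0.55 (lipid), 1.496 (bile acid) and 0.33 (regional factors).

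In progenitor-like cells, distal and proximal genes numbered 15 and 27 with the outer 2 of 4 parts of the score and 2 and 6 with the score thinned to 3000 units, where the antimicrobial median was 0.42. A pseudocount of 10 gave 5 distal genes. The stricter filter gave 19 proximal genes and -0.23 (fatty acid oxidation), and antimicrobial members from 1 ppm gave 0.87. Leaving out barcode sets in turn gave 8 to 14 distal genes, with 14 without set 7, and housekeeping medians of -0.11 (without set 6) to -0.059.

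With the proximal scoring genes alone, 0 progenitor genes were distal and 56 proximal. Medians were -0.89 (lipid), -0.70 (carbohydrate), -0.30 (iron and calcium), -0.42 (retinoid) and -0.69 (drug). Cholesterol (-0.28), peptide (-0.82), bile acid (-0.60), antimicrobial (-0.17) and villus tip (-0.26) changed sign, as did Fabp6 (-0.60), Reg3g (-0.13), Reg3b (-0.033) and Gkn3 (0.068). With the distal scoring genes alone, 51 were distal and 6 proximal. Medians were 0.47 (cholesterol), 0.94 (peptide), 1.91 (bile acid) and 0.71 (villus tip). Lipid (0.81), iron and calcium (0.38) and retinoid (0.30), which were not called, and carbohydrate (0.30), drug (0.47), fatty acid oxidation (0.10) and MHC class II (-0.027) changed sign, as did Fabp1 (0.23), S100g (0.065), Reg1 (0.51) and Arg2 (0.21).

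Without rescaling, the progenitor fatty acid oxidation median was -0.045, and housekeeping, not called, changed sign to 0.0075. Without cluster 7 there were 20 proximal genes, with 0.080 (peptide) and -0.48 (drug). With unnamed cluster 2 added, medians were 0.48 (peptide), 0.10 (regional factors) and -0.16 (housekeeping), and drug metabolism changed sign to 0.042. Without barcode sets 4 and 7, 1653 of the 1692 enterocyte genes and all 21 progenitor genes stayed past the rule in the same direction.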

Other observations

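The genes, clusters and comparisons in this part were chosen after the data had been seen. Tuft-like cells formed a pair of clusters that came from different barcode sets. Cluster 21 held 340 cells, 317 of them from set 7, and cluster 24 held 75 cells, 67 of them from set 4. Dclk1, Rgs13 and Sh2d6, all tuft cell markers, were among the leading genes of both. Genes higher in cluster 24 included Rbp2 at 7505 ppm against 320 in cluster 21, the apolipoprotein gene Apoc2 at 3402 against 108, the lactase gene Lct at 307 against 9.28 and Leap2, which encodes a ghrelin receptor antagonist, at 390 against 8.70. Genes higher in cluster 21 included the histone gene Hist1h2ap, at 263 ppm against 14.3 in cluster 24. Lct is among the enterocyte markers, and enterocyte-like cells were 34.0% of set 4 and 4.89% of set 7. Neither free RNA of enterocytes nor any remaining doublets were separated from this difference, and no gene list was tested. The clusters and the sets coincide, so a difference between tuft-like cells and one between libraries cannot be separated here.

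Some genes differed in opposite directions in the classes. In all 8 barcode sets of both classes, 52 of 7254 genes had opposite signs, fewer than the 194 that independent directions would give. The same scoring genes ordered both classes, so their directions were not independent. Slc13a1, a sulfate transporter gene, was higher distally in enterocyte-like cells (0.90) and lower distally in progenitor-like cells (-0.95). The interferon-induced gene Ifitm3 was at 0.99 and -0.65. It is among the leading genes of a progenitor-like cluster rich in stem markers at resolution 0.5, and stem markers themselves were at 1.55 in enterocyte-like and -0.15 in progenitor-like cells. The cytochrome P450 gene Cyp4f40 (-1.35 and 0.71) and the glutathione transferase gene Mgst2 (-1.26 and 0.42) had the reverse, as did the mitochondrially encoded mt-Nd1 (-0.67 and 0.31). The difference between the classes was not tested.

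Several unnamed clusters carried regional or technical marks. Cluster 2 (2796 cells, 10.0%) was led by noncoding transcripts such as Kcnq1ot1, with a median of 13.6% mitochondrial transcripts. Cluster 9 (1197 cells, 4.30%) was led by genes that included Car4, Gstm3 and Reg3a, and cluster 12 (1089 cells, 3.91%) by genes that included Car1, Fabp6 and Reg3b. Cluster 19 (361 cells, 1.30%) was led by genes that included Meis2, Onecut2 and Dmbt1.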
